A study of Homo sapiens with 24 samples.

How the data were processed

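RNA of MUG and UCH7, a pair of established human chordoma cell lines, was sequenced after DMSO or KDOBA67. Chordoma is a bone tumour of notochordal type that expresses brachyury, the product of TBXT. Libraries were made from Trizol-extracted total RNA with a NEBNext Ultra kit, per the labels' protocols. The dose and duration of KDOBA67 are not given in the sources used here. The labels give 24 samples in 2 count tables, called the first and the second table here. Each table holds 12 libraries, with 3 per combination of line and treatment. Groups and replicate numbers came from the labels alone.

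Both tables hold raw read counts per Ensembl gene as the authors deposited them, with no normalization. The second table is featureCounts 1.4.6-p3 output, per the file headers. It counted read pairs by primary alignment, ignored reads marked as duplicates and set no strand option. Its gene models were Ensembl GRCh38 per the same header, whereas the submitters' processing notes name HISAT2 2.1.0 and hg19. Coordinates below are those of that table. The counter and gene models of the first table are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Counting by primary alignment can also split reads among near-identical genes, so values of metallothioneins, AKR1B10 and AKR1C1, the RFPL4A and PSG families, and mitochondrial genes with nuclear copies are uncertain. Ignoring duplicates can lower the counts of the most abundant transcripts.

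The first table lists 20167 genes and the second 60675, and 19432 are in both. Symbols from a gene-name table matched 19299 and 56558 of them. Total counts were 17562905 to 23477018 per library in the first table, except for 111470149 in the library labelled MUG KDOBA67 replicate 3. They were 9761442 to 14328766 read pairs in the second. The level of 3 counts in the shallowest library was 0.171 CPM in the first table and 0.307 CPM in the second. Such floors, and the counting intervals given below, cover counting error only.

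Whether the tables hold the same libraries was checked on 8256 genes. For each pair of libraries, the variance of the difference was divided by that expected from counting alone. Each of the 12 libraries of the first table had its own best match in the second, with ratios of 0.651 to 2.37, and 9 of the ratios were under 1. The next best matches had ratios of 2.55 to 21.3. In counts simulated at the depth of the second table, a library drawn again gave 1.00 and the closest other library 2.54. The tables were therefore counted as the same 12 libraries, with n = 3 per group, and no fit pooled them. The group label was the same in both tables for only 4 of the 12 libraries. No library was regrouped by its values: each table was analysed under its own labels, and results of the first are given as labelled. The account leads with the second table, whose replicates correlated at 0.981 or higher in each group, against values as low as 0.803 in the first. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

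Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group, a robust quasi-likelihood fit of all 12 libraries of a table with a mean per group, and Benjamini-Hochberg adjustment. This tested 14271 genes in the first table and 18029 in the second, and a gene was called at an adjusted p of at most 0.05. The contrasts were KDOBA67 against DMSO in each line, and the difference between these effects, UCH7 minus MUG. CPM values use the TMM factors and are given as mean ± SD, and log2 changes as value ± SE. A set of 27 pathway lists and 6 lists of other cell types was tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Lists with fewer than 5 measured members were not tested. These lists and the tests were fixed before the data were examined.

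Genes to name were chosen by a rule fixed at the same time. It took TBXT, KDM6A and KDM6B, the 10 rising and 10 falling genes with the largest change among called genes with at least 5 CPM in a group and no overlap between treatments, up to 4 members per list with the smallest adjusted p, and the 10 genes with the smallest adjusted p for the difference between lines. Placeholder and clone symbols and those of microRNAs, small nucleolar, small nuclear and signal recognition particle RNAs, long non-coding RNAs named as intergenic or host genes, and antisense transcripts were left out of the ranking by change. Mitochondrial transfer RNAs, pseudogenes and genes without a symbol were not left out. The rule asked for genes called in both tables, or in each table alone if these proved to hold the same libraries. The second form was used, for all parts of the rule. Some genes that the rule took are not reported here.

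On simulated counts with 4-fold changes, the steps for the second table recovered 87.9% of the changed genes in MUG, 89.4% in UCH7 and 78.8% for the difference, over 18029 genes. For 2-fold changes the shares were 65.7%, 62.7% and 43.3%. For the first table, over 14271 genes, 4-fold changes were recovered for 21.2% in MUG, 13.6% in UCH7 and 0% for the difference. Each simulation changed only 66 or 67 genes per size of change. For the second table it called 90 to 129 genes, far fewer than were called in the data. Recovery in the data may therefore differ from these shares. Alternatives covered DESeq2 1.42.0, other scaling factors and filters, the replicate number as a block, fits of single lines, other list tests, and leaving out each library.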

Results

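Chordoma cells of the lines MUG and UCH7 were compared after DMSO, the solvent control, and KDOBA67, an inhibitor of the H3K27 demethylases KDM6A and KDM6B. The series asks what inhibiting these enzymes does to brachyury (TBXT) and to the cells. Its design text speaks of 3 chordoma lines, and libraries of MUG and UCH7 were analysed here. The second table had 9761442 to 14328766 read pairs per library. The first had 17562905 to 23477018 counts per library, apart from 1 library with 111470149.

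Each of the 12 libraries of the first table matched its own library of the second, but under conflicting labels. For those labelled MUG KDOBA67 replicates 1 and 3 in the first table, mixing with libraries of the same group, or in a small share, stays open. The 3 libraries labelled UCH7 KDOBA67 carried the same label and number in both. The library labelled UCH7 DMSO replicate 1 in the first table matched UCH7 DMSO replicate 3 in the second. The other 8 had a different group label, and 4 of these a different cell line. For example, the library labelled MUG DMSO replicate 1 in the first table matched UCH7 DMSO replicate 2 in the second. Statements drawn from the second table therefore depend on its labels. No MUG library carried the same group label in both tables, and of the 3 UCH7 DMSO libraries only replicate 3 did. A fit of only the 4 libraries with the same group label, a restriction chosen after seeing the data, left out 2 UCH7 DMSO libraries and all 6 MUG libraries. It called 1057 genes in UCH7, against 6527 with all 12 libraries and 5729 with the 6 UCH7 libraries alone.

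**Figure D1:**
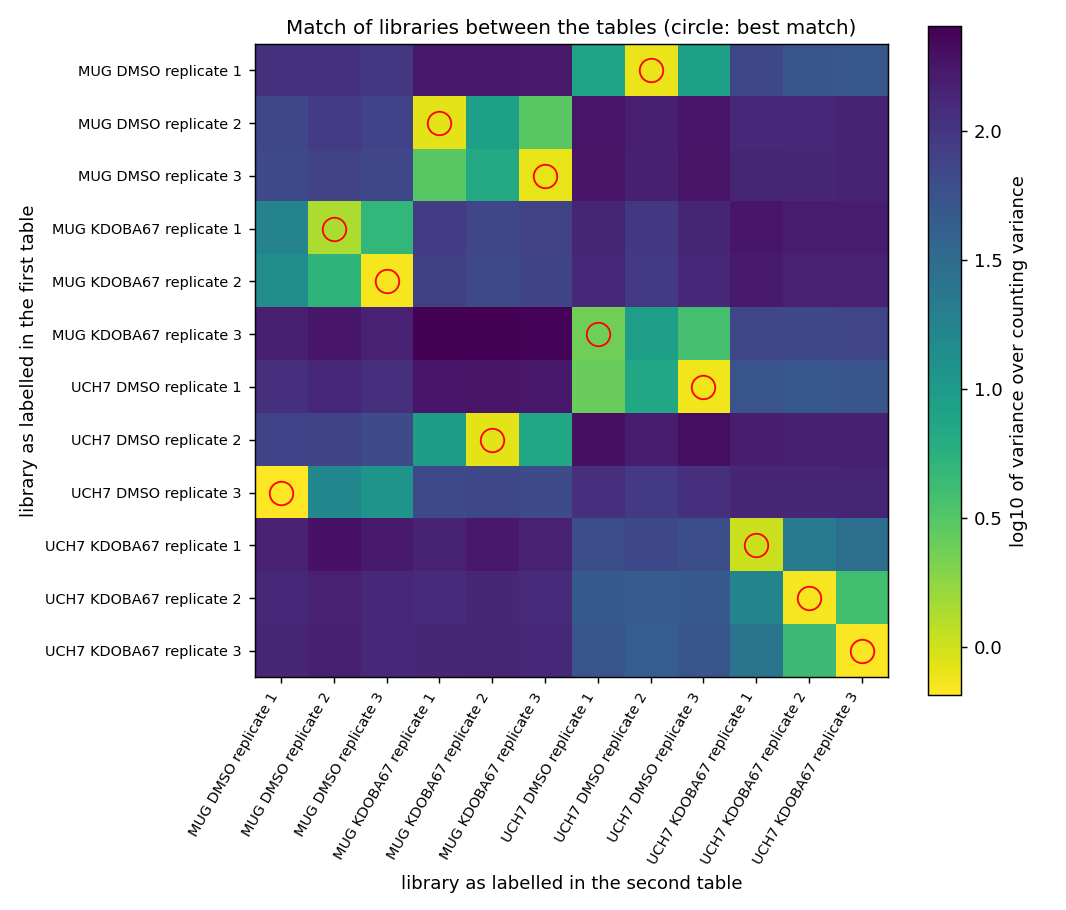
Each cell compares a library of the first table (vertical axis, as labelled) with a library of the second (horizontal axis, as labelled), as the log10 of the variance between them over the variance expected from counting. Circles mark the best match of each library of the first table, whose ratios were 0.651 to 2.37. Only 4 of the 12 circles lie where the group labels agree.

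TBXT, the gene of the notochord transcription factor brachyury, fell with KDOBA67 in both lines of the second table. Its gene (ENSG00000164458) lies on the minus strand of chromosome 6 from 166157656 to 166168700 in GRCh38. In MUG it went from 642 ± 17.95 CPM to 221 ± 1.42 CPM (SD, n = 3), a log2 change of -1.54 ± 0.07 (edgeR adjusted p = 2.98e-09). In UCH7 it went from 1539 ± 80.3 to 598 ± 19.1 CPM, a change of -1.36 ± 0.07 (edgeR adjusted p = 1.06e-08). The test of the difference between the lines did not pass (0.18 ± 0.10, edgeR adjusted p = 0.231). On the 4 libraries with the same group label in both tables, a restriction chosen after seeing the data, the change in UCH7 was -1.36 with the counts of the second table and -1.45 with those of the first. These are the same libraries counted in each table, 1 DMSO against 3 KDOBA67, with the spread taken from the KDOBA67 libraries alone, so they add no separate evidence.

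Of the inhibitor's targets, KDM6A rose in MUG, and KDM6B rose in UCH7. KDM6A (ENSG00000147050, chromosome X, 44873177 to 45112602, plus strand) went in MUG from 20.3 ± 4.36 to 45.7 ± 3.23 CPM, a log2 change of 1.17 ± 0.14 (edgeR adjusted p = 1.58e-05). In UCH7 it was at 32.4 ± 3.78 and 41.2 ± 3.55 CPM (0.34 ± 0.14, edgeR adjusted p = 0.0721; range over its alternatives 0.0226 to 0.455). It was called up in UCH7 in the fit of UCH7 alone (0.35, edgeR adjusted p = 0.0412) and with upper-quartile factors (0.37, edgeR adjusted p = 0.0434). The difference between the lines passed the test (edgeR adjusted p = 0.00844). KDM6B (ENSG00000132510, chromosome 17, 7839904 to 7854796, plus strand) had 1 read in the 3 DMSO libraries of MUG together and 0 in the 3 KDOBA67 libraries, so no fold is given. In UCH7 it had 485 and 806 reads, a log2 change of 0.74 ± 0.21 (edgeR adjusted p = 0.0189; range over its alternatives 0.000122 to 0.386). That call ended without UCH7 DMSO replicate 1 (0.70, edgeR adjusted p = 0.0639) or UCH7 DMSO replicate 2 (0.70, edgeR adjusted p = 0.06), and on the 4 libraries with the same group label (0.61, edgeR adjusted p = 0.386), and the change was 0.44 without UCH7 KDOBA67 replicate 1.

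**Figure D2:**
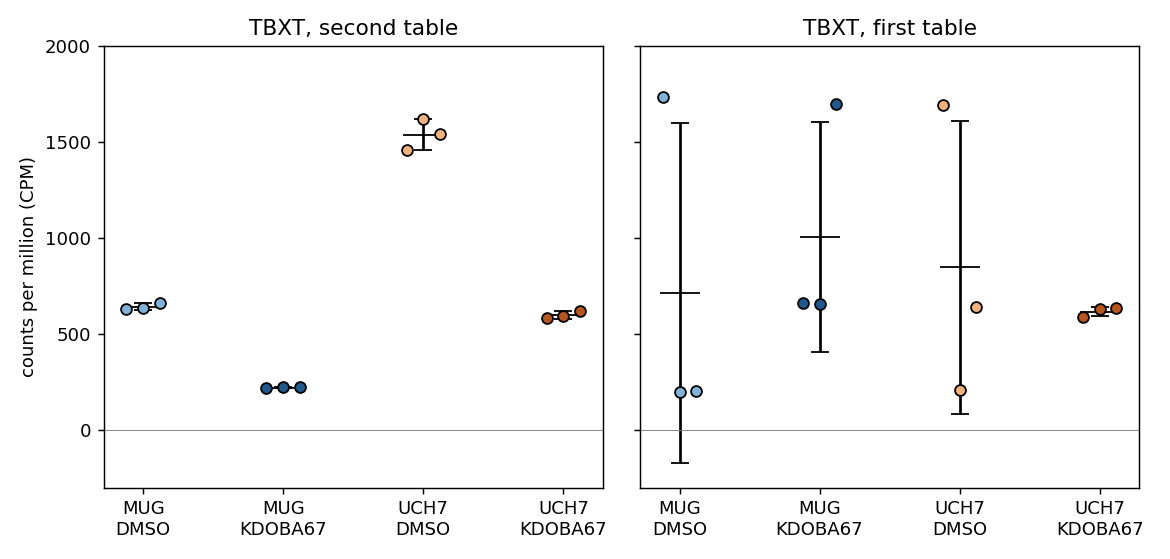
TBXT in CPM for each library, grouped by the labels of the second table (left) and of the first (right). Points are libraries, horizontal bars group means and whiskers 1 SD (n = 3). Group means in the second table lie between 221 and 1539 CPM, while the MUG DMSO group as labelled in the first table spans 199 to 1734 CPM.

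In MUG, KDOBA67 changed 9305 of 18029 genes in the second table, 4522 up and 4783 down (edgeR), and 3092 of them by at least 2-fold. Among the 10 largest rises were SPINK1, a secreted protease inhibitor, from 0.594 ± 0.204 to 31.7 ± 3.91 CPM, and COL17A1, a hemidesmosome collagen, which rose by 4.95 ± 0.35 on the log2 scale. SLAMF7, a cell-surface receptor, rose from 6.14 ± 0.371 to 122 ± 3.55 CPM. RFPL4A had 3 reads over the DMSO libraries and 334 over the KDOBA67 libraries, a ratio of 104 (95% counting interval 35.4 to 508). RFPL4AL1, PSG6, SLC30A3, DNAH6 and an unnamed gene (ENSG00000236453) were also among these 10.

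The largest falls in both lines were of transcripts of the mitochondrial genome, among them MT-TC, MT-TN, MT-TY and MT-TP, which encode transfer RNAs, and of nuclear copies that can share their reads (MTCO3P12 in MUG, MTCO1P12 in UCH7). All 13 measured mitochondrial mRNAs fell in each line, over all genes and adjusted over the list alone, with a median log2 change of -4.45 in MUG and -5.64 in UCH7. MT-CO1, a subunit of cytochrome c oxidase, went from 4700 ± 188 to 94.7 ± 6.43 CPM in MUG and from 3875 ± 270 to 51.4 ± 7.33 CPM in UCH7. MT-CO2 fell by 5.15 ± 0.11 in MUG and by 5.32 ± 0.11 in UCH7 on the log2 scale. These 13 mRNAs made up 2.32% to 2.53% of counts in the MUG DMSO libraries and 0.103% to 0.109% in the MUG KDOBA67 libraries. In UCH7 they made up 1.79% to 1.94% and 0.0348% to 0.0480%. The list was fixed as a sign of RNA quality, so this difference runs alongside each gene group below. Nuclear-encoded oxidative phosphorylation genes had medians of -0.25 in MUG (4 rose and 11 fell of 57, or 3 and 5 when adjusted over the list alone, camera adjusted p = 0.195) and -0.43 in UCH7 (0 rose and 19 fell, or 0 and 18 adjusted over the list alone, camera adjusted p = 8.01e-06, adjusted p = 0.588 with an estimated correlation).

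Notochord and chordoma markers fell in MUG: 28 of the 36 measured members fell and 0 rose, or 29 fell when adjusted over the list alone, with a median of -0.90 (camera adjusted p = 2.88e-09). FOXA1, a forkhead factor of the notochord, went from 115 ± 6.83 to 25.7 ± 1.49 CPM. HAPLN1, a cartilage link protein, fell by 2.17 ± 0.09 on the log2 scale and C1QTNF3 by 1.47 ± 0.09. Fibroblast markers moved the same way in MUG: 9 of 11 fell and none rose (median -1.16, camera adjusted p = 0.000385, adjusted p = 0.0305 with an estimated correlation). Of 7 epithelial markers 4 fell and none rose, but that list did not pass (median -1.31, camera adjusted p = 0.239). Endothelial markers had 1 up and 1 down of 6 (camera adjusted p = 0.432). The fall of fibroblast markers runs alongside each gene group given for MUG. In UCH7, 19 of the 36 notochord and chordoma markers fell and 2 rose, or 21 and 2 over the list alone, with a median of -0.59 (camera adjusted p = 6.03e-06). COL2A1, the main collagen of cartilage, went from 21.1 ± 3.08 to 7.26 ± 0.377 CPM in UCH7 and from 1835 ± 120 to 658 ± 57.6 CPM in MUG.

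Genes of the ATF4 response, which serves amino-acid supply and cell stress, rose in both lines. In MUG 37 of 46 rose and 4 fell (38 and 4 over the list alone; mean log2 change 1.11, camera adjusted p = 7.8e-13), and in UCH7 40 rose and 2 fell (42 and 2; mean 1.52, camera adjusted p = 2.76e-24). ATF3, a stress-induced transcription factor, went from 15.8 ± 0.635 to 154 ± 1.37 CPM in MUG and from 24.1 ± 1.17 to 141 ± 16.9 CPM in UCH7. GDF15, a secreted stress cytokine, went from 37.2 ± 1.83 to 559 ± 52.9 CPM in UCH7, and SESN2 rose by 2.26 ± 0.08 and 2.27 ± 0.08 in MUG and UCH7. TRIB3, a pseudokinase, rose by 5.12 ± 0.17 in UCH7 and 2.75 ± 0.12 in MUG, and ASNS, asparagine synthetase, by 2.15 ± 0.08 and 0.78 ± 0.08.

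Mitotic genes fell in both lines: 37 of 45 in MUG (38 over the list alone; median -0.94, camera adjusted p = 3.07e-14) and 41 of 45 in UCH7 (43 over the list alone; median -0.90, camera adjusted p = 1.32e-21), with no member rising. PLK1, a mitotic kinase, went from 81.7 ± 2.92 to 14.9 ± 1.31 CPM in MUG and from 134 ± 6.75 to 38.5 ± 1.44 CPM in UCH7. CDC20, an activator of the anaphase-promoting complex, fell by 2.01 ± 0.09 and 1.75 ± 0.09, and CCNB1, cyclin B1, by 1.43 ± 0.08 and 1.37 ± 0.08. Genes of DNA replication went both ways in MUG (19 rose and 16 fell of 58, the same over the list alone, camera adjusted p = 0.468). In UCH7 4 rose and 28 fell, or 4 and 30 over the list alone (median -0.29, camera adjusted p = 1.84e-05, adjusted p = 0.0823 with an estimated correlation), among them RRM2, a ribonucleotide reductase subunit, by 1.39 ± 0.09, UHRF1 by 1.25 ± 0.10 and TK1 by 1.26 ± 0.11.

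The hypoxia list moved in opposite directions. In MUG 31 of 42 members rose and 0 fell, with the same counts over the list alone (median 0.85, camera adjusted p = 1.73e-11). NDRG1 rose by 2.64 ± 0.09 on the log2 scale, ADM, adrenomedullin, from 10.9 ± 0.239 to 64.7 ± 0.864 CPM, and VEGFA, an angiogenic growth factor, from 63.1 ± 4.87 to 279 ± 7.89 CPM. In UCH7 5 rose and 30 fell, or 6 and 31 over the list alone (median -0.59, camera adjusted p = 2.88e-08). PGK1 and LDHA, enzymes of glycolysis, fell by 1.20 ± 0.08 and 1.32 ± 0.09, while VEGFA rose there too, by 1.02 ± 0.08. These named members had higher levels in UCH7 than in MUG with DMSO. NDRG1 was at 86.8 CPM in MUG DMSO and 369 in UCH7 DMSO, and PGK1 at 611 and 1391. ADM was at 10.9 and 97.4, LDHA at 1233 and 2422, and VEGFA at 63.1 and 108. With KDOBA67, NDRG1 was at 541 and 473 CPM and PGK1 at 831 and 607. How far the opposite changes reflect unlike DMSO levels was not tested. The difference between the lines passed the test for 40 of the 42 members, or 41 adjusted over the list alone, all with the lower change in UCH7 (median -1.13, camera adjusted p = 8.53e-28, adjusted p = 0.00966 with an estimated correlation).

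Several other lists passed in MUG. Of 12 lists called in MUG with the preset correlation, 8 were also called with an estimated one: notochord, ATF4, hypoxia, cholesterol, G2/M, mitochondrial, immediate early and fibroblast. Immediate early genes rose (18 up and 2 down of 24, with the same counts over the list alone; camera adjusted p = 1.29e-06), with JUN from 82.5 ± 2.30 to 229 ± 9.89 CPM, KLF4 up by 1.41 ± 0.09 and MAFF by 2.49 ± 0.18. Cholesterol synthesis genes fell (25 of 35, or 27 over the list alone, none up; camera adjusted p = 8.47e-08), among them FADS2, a fatty acid desaturase, by 1.96 ± 0.09 and MSMO1 by 0.89 ± 0.08. The fibroblast markers fell (9 of 11, or 10 over the list alone, none up; camera adjusted p = 0.000385), with LUM down by 1.34 ± 0.09, DCN down by 1.63 ± 0.12 and PDGFRB by 1.44 ± 0.14. NRF2 antioxidant targets fell in MUG (4 up and 16 down of 28, or 4 and 19 over the list alone, camera adjusted p = 0.00294, adjusted p = 0.402 with an estimated correlation); AKR1B10 fell by 2.13 ± 0.12, while HMOX1, heme oxygenase, rose by 1.99 ± 0.12. Autophagy and lysosome genes rose (24 up and 5 down of 42, or 25 and 5 over the list alone, camera adjusted p = 0.00039, adjusted p = 0.077 with an estimated correlation), with MAP1LC3B up by 1.81 ± 0.08. Of the JmjC demethylases outside the KDM6 family, 11 of 20 rose and 1 fell, or 13 and 1 over the list alone (camera adjusted p = 0.0199, adjusted p = 0.611 with an estimated correlation), KDM3A by 1.37 ± 0.12 and JMJD6 by 0.93 ± 0.09. HOX genes fell (2 up and 12 down of 29, the same over the list alone, camera adjusted p = 0.0207, adjusted p = 0.118 with an estimated correlation).

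In UCH7, KDOBA67 changed 6527 of 18029 genes, 3252 up and 3275 down (edgeR), and 1949 of them by at least 2-fold. Among the 10 largest rises were TRIB3, HKDC1, a hexokinase-like protein, from 0.531 ± 0.266 to 16.7 ± 1.38 CPM, and FST, follistatin, from 0.405 ± 0.203 to 8.02 ± 0.231 CPM; the others were MT1H, SPRR2D, IL36RN, MT1G, KLHDC7B, CEACAMP10 and CD244. Targets of p53 rose (27 up and 1 down of 30, with the same counts over the list alone, median 0.96, camera adjusted p = 1.18e-14), with CDKN1A, a cyclin-dependent kinase inhibitor, from 287 ± 10.2 to 994 ± 55.7 CPM (1.79 ± 0.08), BTG2 up by 1.59 ± 0.09 and AEN by 0.94 ± 0.07. CDKN1A and AEN rose more in MUG, by 2.34 ± 0.08 and 1.71 ± 0.07, while BTG2 was not called there (-0.14 ± 0.10, edgeR adjusted p = 0.26). Metallothioneins and zinc transporters rose (7 up and 1 down of 12, or 9 and 1 over the list alone; camera adjusted p = 2.02e-05), with MT2A from 71.7 ± 6.80 to 375 ± 31.8 CPM, MT1G up by 4.66 ± 0.22 and SLC30A1, a zinc exporter, by 1.21 ± 0.08. NF-kB and inflammatory genes rose (17 up and 1 down of 27, or 20 and 2 over the list alone; camera adjusted p = 5.27e-08), with IRF1 up by 1.37 ± 0.08, RELB by 1.31 ± 0.09 and TNFAIP2 by 1.79 ± 0.14. Autophagy and lysosome genes rose (21 up and 1 down of 42, or 23 and 1 over the list alone, camera adjusted p = 3.46e-05), with SQSTM1 up by 1.41 ± 0.10.

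Of 19 lists called in UCH7, 9 were also called with an estimated correlation: notochord, ATF4, metallothionein, hypoxia, p53, G2/M, NF-kB, autophagy and mitochondrial. For the others the call was lost. NRF2 antioxidant targets had 21 up and 1 down of 28, the same over the list alone (camera adjusted p = 2.14e-08, adjusted p = 0.062 with an estimated correlation), with OSGIN1 up by 2.05 ± 0.11, SLC7A11, the cystine transporter, by 1.89 ± 0.11 and AKR1C1 by 1.43 ± 0.12. Cholesterol synthesis genes had 4 up and 18 down of 35, or 4 and 20 over the list alone (camera adjusted p = 4.81e-05, adjusted p = 0.0746 with an estimated correlation), with MSMO1 down by 1.03 ± 0.08. Immediate early genes had 12 up and 3 down of 24, or 13 and 3 over the list alone (camera adjusted p = 0.0017, adjusted p = 0.082 with an estimated correlation), with SIK1 up by 1.41 ± 0.11. The preset calls of interferon response (14 up and 1 down of 37), iron handling (7 up and 1 down of 13), apoptosis regulators (15 up and 6 down of 34), heat shock (4 up and 16 down of 30) and ribosomal protein genes (0 up and 5 down of 74) had estimated-correlation adjusted p values of 0.588, 0.38, 0.144, 0.444 and 0.75. Adjusted over the list alone, their counts up and down were 15 and 1, 7 and 2, 16 and 6, 4 and 18, and 0 and 2.

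The remaining lists passed in neither line or in 1 line only, and are given as counts of genes up and down. H3K27 demethylases and Polycomb genes had 8 and 8 of 29 in MUG and 6 and 7 in UCH7, EGFR and MAPK feedback genes 13 and 8 of 30 and 10 and 10, and endoplasmic reticulum chaperones 8 and 11 of 33 and 10 and 13. TGF-beta, YAP and matrix genes had 13 and 22 of 43 in MUG and 10 and 8 in UCH7, brachyury-linked growth factors 7 and 10 of 24 and 8 and 7, and replication-dependent histones 1 and 7 of 11 and 1 and 4. In MUG alone, metallothioneins had 5 and 4, NF-kB genes 13 and 5, p53 targets 10 and 8, apoptosis regulators 16 and 5, iron handling 6 and 2, heat shock 8 and 15, interferon response 6 and 5 and ribosomal protein genes 0 and 4. In UCH7 alone, HOX genes had 2 and 7, other JmjC demethylases 2 and 3 and fibroblast markers 2 and 1. Epithelial markers had 0 and 4 of 7 in MUG and 2 and 1 in UCH7, and endothelial markers 1 and 1 of 6 and 0 and 0. Leukocyte, neural and bone and muscle lists had only 4, 3 and 2 measured members and were not tested. Adjusted over the list alone, the counts in MUG that differed were 14 and 22 for TGF-beta, 7 and 2 for iron, 10 and 9 for p53, 8 and 16 for heat shock, 5 and 5 for interferon and 0 and 1 for ribosomal protein genes. In UCH7 they were 12 and 10 for EGFR, 11 and 14 for chaperones of the endoplasmic reticulum, 11 and 8 for TGF-beta, 9 and 8 for brachyury-linked genes and 2 and 2 for other JmjC demethylases. Median, mean and test had the same sign for every list called in a line of the second table. Among lists not called they differed in sign for the H3K27 demethylase and Polycomb list in MUG, and for the HOX, fibroblast and brachyury-linked lists in UCH7.

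**Figure D3:**
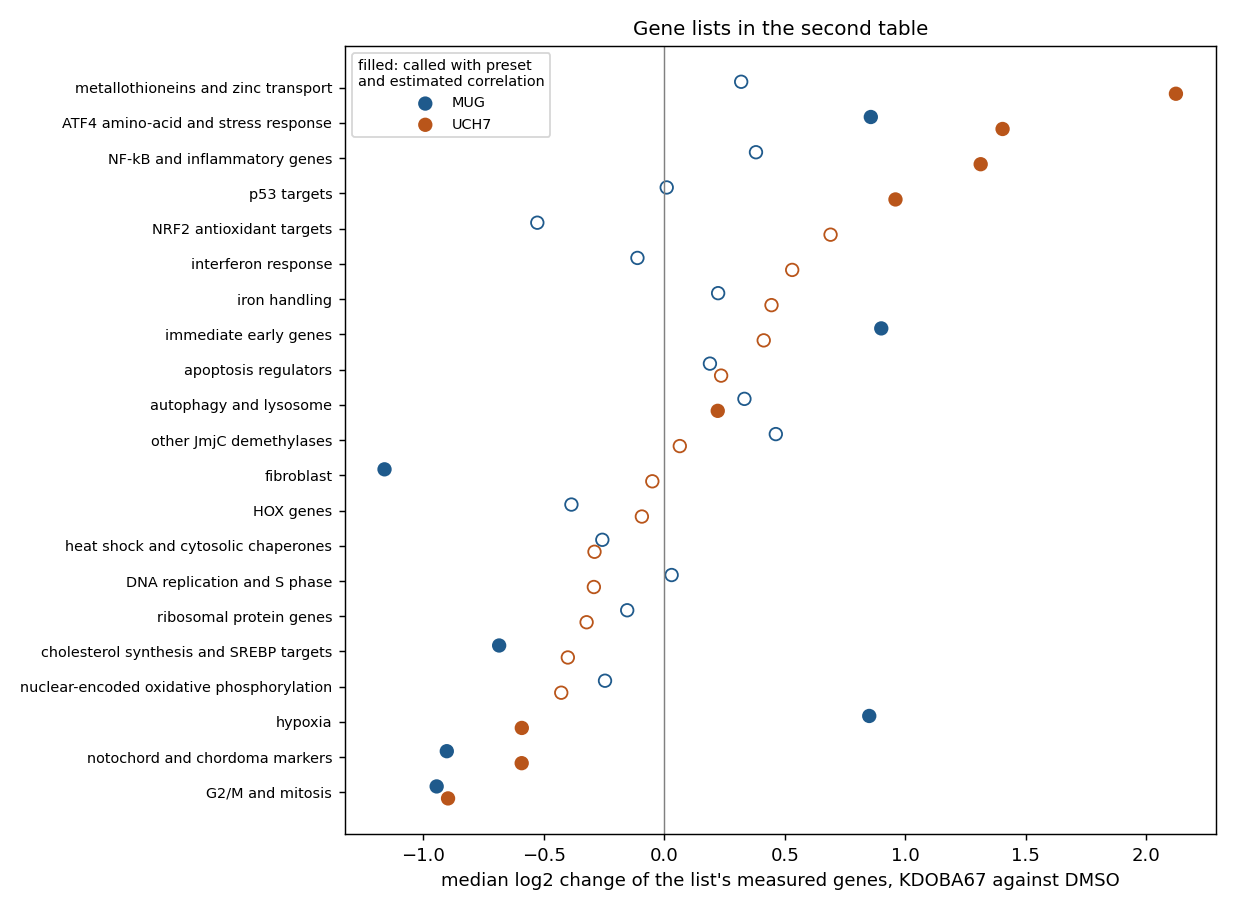
Median log2 change of each list's measured genes in MUG and UCH7, for lists called in at least 1 line of the second table, leaving out the mitochondrial mRNAs (medians -4.45 and -5.64). Filled points passed with both the preset and an estimated correlation. The hypoxia list lies at 0.85 in MUG and -0.59 in UCH7.

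The difference between the lines was called for 4373 genes in the second table, 2113 with the higher value in UCH7 and 2260 with the higher value in MUG (edgeR). With upper-quartile factors these counts were 2785 and 1796, so the split by direction depends on the scaling. IGFBP3, an insulin-like growth factor binding protein, rose in MUG by 2.57 ± 0.10 and fell in UCH7 by 0.79 ± 0.10 (edgeR adjusted p of the difference 3.81e-08). CITED2, ARRDC3 and PFKFB4 also rose in MUG, by 1.28 ± 0.08, 1.66 ± 0.10 and 1.30 ± 0.09, and fell in UCH7 by 1.04 ± 0.08, 0.85 ± 0.09 and 1.16 ± 0.10. AKR1B10 fell in MUG and rose in UCH7 by 1.16 ± 0.11. FST and LRATD1 fell in MUG by 0.65 ± 0.10 and 0.83 ± 0.12 and rose in UCH7 by 4.21 ± 0.21 and 2.82 ± 0.13, and GPNMB, a membrane glycoprotein, rose in both, by 0.66 ± 0.09 and 3.68 ± 0.11. NDRG1 and ADM completed the 10 genes with the smallest adjusted p. The NRF2, p53 and fibroblast lists were higher in UCH7 relative to MUG with either correlation (camera adjusted p = 7.37e-15, 4.61e-06 and 0.000164), though the p53 targets CDKN1A and AEN rose more in MUG.

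Both lines shared many changes. Of the called genes, 1829 rose in both lines and 2000 fell in both, against 816 and 869 for independent lists of the same sizes. The numbers with opposite directions were 253 and 301, against 821 and 863. The lines had separate DMSO libraries. The correlation of log2 changes across genes, which are not independent replicates, was 0.511.

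**Figure D4:**
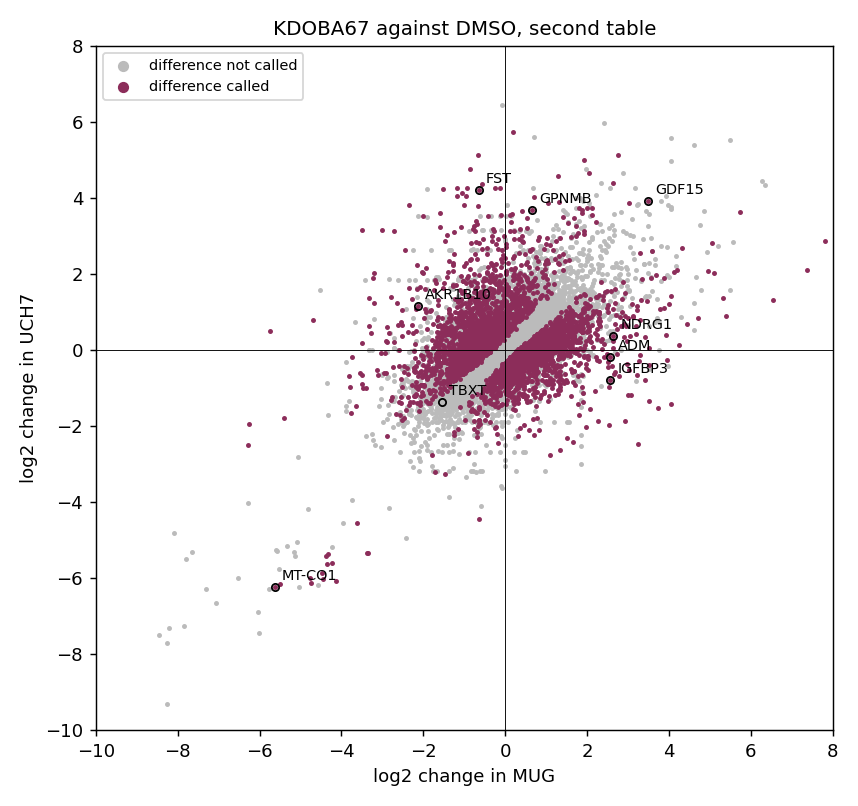
Log2 change with KDOBA67 in MUG (horizontal) and UCH7 (vertical) for the 18029 genes tested in the second table. Dark points are the 4373 genes whose difference between lines was called. TBXT lies near the diagonal at -1.54 and -1.36.

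Under the labels of the first table, few genes passed. Of the libraries labelled UCH7 DMSO there, replicates 2 and 3 matched MUG libraries of the second table. The groups labelled MUG DMSO and MUG KDOBA67 each held a library matched to UCH7 DMSO. If the second table's labels are right, the contrasts of the first table mix cell line with treatment, and their calls are no separate result. In MUG 0 genes were called by edgeR and 0 by DESeq2, with 903 of 14271 at an unadjusted p under 0.05. In UCH7 42 were called by edgeR, 36 up and 6 down, and 1272 by DESeq2, 440 up and 832 down. The 42 calls became 26 without a filter on low counts and 0 in the edgeR fit of UCH7 alone, where 2698 of 13296 genes had an unadjusted p under 0.05. NRG1, a growth factor of the EGF family, went from 25.1 ± 2.33 to 158 ± 28.0 CPM (edgeR adjusted p = 0.00923), and OSGIN1 rose by 2.61 ± 0.38, MT1G by 5.27 ± 0.73, and RRM2 fell by 1.89 ± 0.29. GREB1, CYP4F3, RRAD, ADM2, PSTPIP2, CHAC1 and UNC13D also rose, and PRKCZ, TUBA1A, SLC16A3, TUBB2A and PGAM1 fell. Each library labelled UCH7 lowered the 42 calls when left out: to 3, 8 and 0 without DMSO replicates 1, 2 and 3, and to 2, 0 and 1 without KDOBA67 replicates 1, 2 and 3. NRG1 was the only gene called by edgeR for the difference between lines, with 2649 at an unadjusted p under 0.05 and 953 called by DESeq2. There 1166 were called without the library labelled MUG KDOBA67 replicate 3, the deepest, 8 without MUG DMSO replicate 1, 5 without UCH7 DMSO replicate 2, and 0 without any 1 of the other 9. The libraries whose removal gave 1166, 8 and 5 each matched a library of the other line in the second table. So did UCH7 DMSO replicate 3, whose removal gave 0.

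TBXT was not called in the first table, at 712 ± 885 and 1005 ± 599 CPM in the groups labelled MUG DMSO and MUG KDOBA67 (edgeR adjusted p = 0.953) and 846 ± 765 and 617 ± 25.6 CPM in UCH7 (edgeR adjusted p = 0.788). KDM6A and KDM6B were not called there either. With the preset correlation 14 lists passed in MUG and 16 in UCH7, and none did with an estimated correlation. In MUG as labelled, the ATF4 and hypoxia lists had medians of -0.59 and -0.35 and the G2/M list 0.47, the opposite signs to the second table, with 0 members called in any list (estimated-correlation adjusted p = 0.393, 0.464 and 0.463). The mitochondrial mRNAs, fixed as a sign of RNA quality, moved with them, at a median of 1.70 in MUG as labelled (camera adjusted p = 6.75e-09, adjusted p = 0.393 with an estimated correlation), against -4.45 in the second table. In UCH7 as labelled their median was -6.09 (camera adjusted p = 3.18e-08, adjusted p = 0.343 with an estimated correlation). The libraries labelled MUG DMSO replicates 2 and 3 here matched MUG KDOBA67 libraries of the second table. Those labelled MUG KDOBA67 replicates 1 and 2 matched MUG DMSO libraries. The opposite signs in MUG therefore follow from the conflicting labels of matched libraries, and are no separate result.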

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

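Of the tests in this part, those of scaling, of duplicate removal, of replicate spread and of mixing, and the counts over other splits were chosen or described only after the results were seen. The difference between the lines was tested for 81 genes named in the report from the second table and passed for 57. The share is no measure of how common differences are. Of these genes, 10 were named for the smallest adjusted p of this same difference, and many others for large changes in a line. Over all 18029 genes tested, 4373 were called, or 24.3%. All values are log2 changes in UCH7 minus those in MUG. In order of adjusted p, they were -3.36 for IGFBP3, 3.28 for AKR1B10, 4.86 for FST, 3.02 for GPNMB, 3.65 for LRATD1, -2.28 for NDRG1, -2.32 for CITED2, -2.76 for ADM, -2.51 for ARRDC3, -2.46 for PFKFB4, -1.64 for PGK1 and 1.37 for ASNS. The next were 1.73 for BTG2, -1.45 for JUN, -1.62 for SLAMF7, 1.32 for HAPLN1, 2.15 for TNFAIP2, -1.37 for LDHA, 2.37 for TRIB3, 1.34 for FADS2, 1.54 for DCN, 1.29 for LUM, -1.12 for VEGFA and -1.46 for KDM3A. These were followed by -0.92 for MAP1LC3B, 1.36 for SLC7A11, 1.83 for AKR1C1, 1.16 for OSGIN1, 0.91 for SLC30A1, 3.08 for HKDC1, -0.77 for AEN, -0.91 for RRM2, 1.18 for MT2A, -1.04 for TK1, 0.77 for FOXA1 and -0.90 for JMJD6. Further values were -0.95 for UHRF1, 2.04 for PDGFRB, 2.62 for MT1G, -2.87 for COL17A1, 0.66 for PLK1, -2.12 for SPINK1, -5.24 for RFPL4A, -0.74 for ATF3, -0.65 for KLF4, -0.55 for CDKN1A, 5.76 for CD244 and -0.65 for MTCO1P12. The last were -0.61 for MT-CO1, -0.82 for KDM6A, -0.94 for MAFF, 1.75 for CEACAMP10, -2.09 for ENSG00000236453, 5.63 for IL36RN, 0.42 for GDF15, 0.42 for SQSTM1 and 0.34 for IRF1. RFPL4A, IL36RN and CD244 had 3 or fewer reads in a group, so their fitted values depend on the prior count. Among the lists, the difference passed for 18, of which 4 (hypoxia, NRF2, p53 and fibroblast) also passed with an estimated correlation. For the others the adjusted p with an estimated correlation was 0.0597 to 0.837. The medians were -1.13 for hypoxia, 1.18 for NRF2 antioxidant targets, 0.66 for p53 targets, -0.38 for DNA replication and S phase, -1.22 for mitochondrially encoded transcripts, 0.38 for ATF4 amino-acid and stress response, 1.39 for metallothioneins and zinc transport, 1.29 for fibroblast and 0.41 for NF-kB and inflammatory genes. The remaining ones were 0.52 for interferon response, 0.28 for TGF-beta, YAP and matrix genes, 0.27 for cholesterol synthesis and SREBP targets, 0.40 for notochord and chordoma markers, -0.27 for other JmjC demethylases, -0.50 for immediate early genes, 1.10 for epithelium, -0.14 for nuclear-encoded oxidative phosphorylation and -0.16 for ribosomal protein genes. In the first table, as labelled, the value for NRG1 was 3.14. That contrast mixes cell line with treatment if the second table's labels are right. In the second table, 3 of 100 drawn splits of the libraries gave as many genes as the 4373 called for the difference between lines, the real one included. The highest other count was 9594, for the split that swapped the treatments of UCH7. That split tested the sum of both treatment effects, so its count is no measure of chance. The other split above the real count gave 4737, with MUG as labelled and UCH7 mixed, and the 10 drawn splits of that kind gave 1600 to 4737. Such splits keep the MUG effect, so the share of splits does not isolate a difference between lines. In the first table, 4 of 100 splits gave as many as the real count of 1, and the highest other was 9. For the comparisons within a line only 10 splits exist, too few for a share under 0.05. In the second table, 1 of 10 reached the real count in MUG (9305, highest other 0) and 1 of 10 in UCH7 (6527, highest other 0). In the first table, 1 of 10 did in UCH7 (42, highest other 0) and all 10 in MUG (0, highest other 0).

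The mitochondrial mRNAs fell with KDOBA67 in both lines of the second table. Library scaling is argued against by the shares of raw counts given above, which use no scaling factors. The highest median under 3 other scalings was -4.42, an outcome that those shares all but fixed. Duplicate removal in the second table's counting could hardly make this fall. It can lower the most abundant transcripts, and these mRNAs were more abundant with DMSO, so the outcome of its test was all but fixed in advance. In the first table the lowest share of these mRNAs in libraries matched to DMSO was 37.8 times the highest in those matched to KDOBA67 in MUG. It was 67.4 times in UCH7, against 21.4 and 37.4 in the second table. The fall was thus larger in the first table. The tables were not counted alike, since the first had 1.57 to 1.89 times the share of the second in the DMSO libraries and 0.919 to 1.04 times in the others. Lower transcript levels of the nuclear genes for mitochondrial transcription and RNA stability stay open: of 30, 14 rose and 6 fell in MUG (median 0.27) and 5 rose and 5 fell in UCH7 (median -0.08), and the bound on the median set beforehand was wrong, since a fall of a single factor need not move a median over members that go both ways. A choice of reads shared by both tables, a difference in RNA handling that ran with treatment, and an effect of KDOBA67 on mitochondrial transcripts themselves stay open.

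The labels of 8 libraries differed between the tables. Libraries mixed with one another in the first table are argued against for 6 of the 8, which had a ratio under 1 to a single library of the second. For the other pair, labelled MUG KDOBA67 replicates 1 and 3 in the first table, ratios were 1.35 and 2.37. These lie between the simulated 1.00 for a library drawn again and 2.54 for the closest other, so they cannot decide. Replicate 3 was 7.97 times as deep as its match, unlike the simulated libraries. A large share of another group is argued against. Replicate 1 had 1 KDM6B read, against 208 or more in libraries matched to UCH7. It had 4.60% mitochondrial mRNAs, against 0.111% or less in those matched to KDOBA67. Replicate 3 had 3.27%, and TBXT at 1697 CPM, against 1734 and 1694 CPM in the others matched to UCH7 DMSO. Mixing within a group or in a small share stays open. Wide replicate spread with the first table's labels right is argued against by how the matched libraries group. Within each group of the second table's labels they correlated at 0.981 or higher. Within groups of the first table's labels, values were as low as 0.803. This holds if the second table's labels were not chosen from the counts. KDM6B cannot decide it: 4 of the first table's 12 libraries lay on the other line's side of 5 CPM. The match of the tables, with 4 libraries under another line, fixed that count. Wrong labels in either table remain a candidate explanation, the step at which labels diverged stays open, and no biological explanation was tested.

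The hypoxia list went up in MUG and down in UCH7 with KDOBA67. Gene length, GC content and expression level are argued against: the median difference of -1.13 was at percentile 0 of 10000 lists matched on these, whose lowest was -0.38. A single library is argued against too, since the median difference stayed at -1.07 or lower whichever of the 12 was left out. The opposite directions rest on the second table's labels, and no MUG library carried the same group label in both tables. In MUG as labelled in the first table the list's median was -0.35, with 0 members called. Wrong labels therefore stay open. A difference between the lines in their response stays open as a hypothesis, as do the unlike DMSO levels of the named members. Culture conditions that differed between the lines, which the labels do not give, stay open too.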

How the results depend on the processing

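The restriction to libraries with the same label in both tables and the removal of mitochondrial genes were chosen after seeing the data. No gene or list reversed direction while called. In the second table the counts of called genes stayed within 1.5 times of 9305, 6527 and 4373 under DESeq2, other scaling factors, other filters, each library left out, and without mitochondrial genes. Fits of a single line gave 9329 in MUG and 5729 in UCH7, and have no value for the difference. The fit of the 4 libraries with the same label, with a lone DMSO library assumed to vary like the others, moved the UCH7 count by more than that, to 1057, of which 1056 were among the 6527. It left out 2 UCH7 DMSO libraries and the 6 MUG libraries together, so it had fewer samples. Called lists rose in MUG from 12 to 23 with fry, and fell in UCH7 from 19 to 9 with an estimated correlation. In the first table the UCH7 count of 42 became 1272 with DESeq2, 26 without a filter, 0 in the fit of UCH7 alone and 975 in the 4 libraries with the same label. Leaving out each library gave 0 to 8. The difference between lines went from 1 to 953 with DESeq2, and to between 0 and 1166 with each library left out. The called lists of the first table went from 14 to 0 in MUG with an estimated correlation and to 0 with fry, and from 16 to 0 and 9 in UCH7. The cause of these changes was not tested. With the replicate number as a block, the first table gave 0 genes in UCH7 and 0 for the difference by edgeR, with 1521 and 1658 at an unadjusted p under 0.05, so the NRG1 calls ended too. The second gave 9822, 7110 and 4818, and KDM6A in UCH7 was called (0.35, edgeR adjusted p = 0.0226). Pairing by number was not clear. Same-number correlations in the second table were 0.379, 0.207 and -0.0298 in MUG and 0.104, -0.126 and -0.121 in UCH7. The highest with another number were 0.0603, -0.0402 and 0.262 in MUG and 0.0479, 0.255 and 0.102 in UCH7. Not every library therefore correlated best with its own number, and with 3 libraries per group pairing cannot be excluded. With upper-quartile factors the median shift per gene for the difference was -0.105 in the first table and 0.0982 in the second. A fit of both tables together was not run because they hold the same libraries, and no MUG value exists for libraries with the same label. Of the 83 single-gene calls lost over all alternatives in the second table, 39 were lost with the 4-library restriction and 41 with a library left out. In simulated counts, 43.3% of 67 genes with a 2-fold change were recovered for the difference between lines. That simulation called 90 genes, far fewer than the 4373 in the data, so recovery in the data may differ.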

Other observations

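The tests of gene families in this part were chosen only after the data were seen, and that of the KDM6B region before its result was. All are in the second table. Of 435 measured genes with ZNF symbols, mostly zinc finger transcription factors, 289 rose and 24 fell in MUG, with a median of 0.63, and 176 rose and 19 fell in UCH7, with a median of 0.33. Their camera adjusted p values were 8.18e-17 and 2.27e-08, and the adjusted p values with an estimated correlation 0.155 and 0.344. Tubulins fell: 7 of 14 in MUG and 11 of 14 in UCH7, with none rising (camera adjusted p = 0.0464 and 3.25e-06, adjusted p = 0.645 and 0.183 with an estimated correlation). Proteasome subunits had 3 up and 14 down of 37 in MUG and 0 up and 15 down in UCH7 (camera adjusted p = 0.103 and 0.000238, adjusted p = 0.823 and 0.93 with an estimated correlation). Protocadherins had 3 up and 25 down of 57 in MUG and 2 up and 13 down in UCH7 (camera adjusted p = 0.00023 and 0.147, adjusted p = 0.645 and 0.93 with an estimated correlation). Mitochondrial ribosomal proteins, encoded in the nucleus, had 16 up and 17 down of 85 in MUG and 3 up and 11 down in UCH7 (camera adjusted p = 0.941 and 0.107). Integrins had 3 up and 16 down of 29 in MUG and 5 and 8 in UCH7, kinesins 10 and 13 of 36 and 8 and 13, and the solute carrier family of mitochondrial carriers 17 and 17 of 46 and 10 and 11. Nucleoporins had 8 and 2 of 21 in MUG and 0 and 4 in UCH7, chaperonin subunits 4 and 2 of 12 and 0 and 6, and eIF3 subunits, which initiate translation, 3 and 1 of 13 and 0 and 2. The camera adjusted p values of these last families within each line were 0.0627 or higher. For the difference between the lines, the camera adjusted p was 0.00673 for integrins, 0.0214 for nucleoporins and 0.0263 for chaperonin subunits. Each of these was 0.499 with an estimated correlation. For kinesins, mitochondrial carriers and eIF3 subunits the camera adjusted p of the difference was 0.0652 or higher.

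KDM6B was at 0 or 1 read in each MUG library of the second table. As a hypothesis, loss of the chromosome 17 region around KDM6B in MUG was weighed. Of 6 flanking genes within 100 kb above 1 CPM in UCH7, 4 were above 1 CPM in MUG, all on the right side, and no gene on the left was above 1 CPM in UCH7, so the left side stays open. The nearest genes on the right were low in MUG: NAA38 had mean values of 0.0415 CPM in MUG and 19.2 CPM in UCH7, and CHD3 3.93 and 56.6 CPM, while TRAPPC1 had 43.9 and 27.9 CPM. CNTROB had 35.3 and 45.6 CPM. Loss of the whole 100 kb on the right is therefore argued against by TRAPPC1 and CNTROB, while a shorter loss that reaches from KDM6B into CHD3 stays open.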
